A study of Oryza sativa Japonica Group with 38 samples.

How the data were processed

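RNA from laser-microdissected tissue of 10-day-old rice seedlings was measured on 38 one-colour Agilent arrays in 13 groups of 3 arrays, with 2 for the stele near the base. Per the labels' protocols, RNA was extracted with the Pico-Pure kit, checked on a Bioanalyzer and labelled with Cy3 by the one-colour Quick Amp procedure. Per the file headers, the scanned images were read with Agilent Feature Extraction 10.5.1.1. The deposited array files hold the processed signal as an intensity, per the file headers background-subtracted and not scaled between arrays, and beside it the mean spot intensity and the median local background intensity. The deposited series table held the log2 intensity minus the array's 75th percentile over all spots, controls included, as checked on the values. Each array had 45151 spots, of which 43734 were not controls, for 42477 probes. The probes named 29689 gene loci of the Rice Annotation Project, and 588 probes named none. The genome reference at hand could not be linked to these loci, so gene names and descriptions came from the array files and genomic positions are not given.

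The log2 processed signal was averaged over the spots of a probe and scaled by subtracting each array's 75th percentile over the probes that were not controls. The percentile differed between arrays from 13.1 to 492 intensity units, and the number of spots that the scanner software marked as well above background from 6480 to 28961. No spot was saturated (0). 153 probes that the scanner software marked as outliers on any array were left out. The probe with the highest mean over all arrays stood for a gene, which left 29611 genes, and the 20399 genes well above background on every array of at least 1 group were tested. With groups of 3 or 2 arrays, the number of arrays limits the precision. The labels do not tie samples to plants, so the p values measure the spread between samples, which may be technical.

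One model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and the data.table package (version 1.17.8). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 within the contrast and a difference of at least 2-fold. The comparisons were the 7 steps along the root, a moderated F test over the 8 stages, the 3 pairs of tissues near the tip, the outer tissue against the stele near the base, the change of that difference between positions, and the base against the tip within each of these tissues. Enriched genes had to pass against every other stage (root cap) or every other tissue near the tip. Where the count fell by more than 1.5 times, the text also gives the number of calls whose higher group was well above background on every array and at least 2-fold over the background floor of the lower group. Where a gene was not well above background on every array of the lower group, its fold is a lower bound: the higher group's mean against the lower group's mean of, on each array, the larger of its own signal and the floor, the lowest signal of a spot well above background on that array. The floor was first taken over probe means, which let in spots not well above background, and was raised after the values were seen.

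Gene lists were defined before the data were examined by words in the gene descriptions, 26 in all. The 25 lists with 5 or more tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and 14 contrasts. Of the 350 tests, 126 passed, and with a correlation estimated per list 0 passed, against 45 at an unadjusted p under 0.05 and 200 with fry, which asks whether the genes of a list move one way and does not compare them with other genes. A count adjusted over the list alone used the members as the only genes tested. The genes named were bound by a rule fixed before the data were examined. It allowed 46 marker genes, of which 42 were tested and 2 had no probe, while the others were too dim to test. It also allowed up to 4 passing members of each list with the largest difference, and up to 8 genes in each direction with the largest difference, a named product and every array of the higher group above every array of the lower. In enriched sets it allowed the 12 genes with the largest difference to the nearest other group.

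After the data were seen, the rule was applied separately to genes well above background in both groups and to genes near background in the lower group, which were ranked by their bound. Of 352 namings in the report and closing section, 124 were markers, 133 followed the rule as first written, and 95 came only from this later extension, so they were chosen after their values were seen. Among the genes allowed, those whose call ended when 1 array was left out were mostly not named, which was also decided after their values were seen. The files describe the marker genes LSI2, CASP1 and NAR2.1 as hypothetical, NRT2.1 as BCH2 and NRAMP5 as OsNramp1, and they were kept.

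The alternatives fixed beforehand were scaling on the median, quantile normalization, normexp background correction with an offset of 50, the deposited series table, no filter on dim probes, only genes well above background on every array, every probe counted on its own, blocks for replicate number and slide, a variance trend with robust fitting and array weights, only the arrays compared, and leaving out each array in turn. The arrays lay on 11 slides scanned on 2 days. Same-numbered samples were not treated as pairs: the mean correlation of their deviations between compared groups was -0.0125. That value does not show whether such samples came from the same plants. The pipeline was tested on simulated data of 20399 genes with 200 changed. For the stele against the cortex, changes of 2.83-fold, 4-fold and 8-fold were recovered in 65.7%, 85.1% and 93.9% of genes, and 8 unchanged genes were called. For the outer tissue against the stele near the base these shares were 52.2%, 70.1% and 89.4% with 6 unchanged genes called, for the interaction 38.8%, 50.7% and 78.8% with 8, for the F test 44.8%, 73.1% and 97% with 4, and for the root cap set 37.3%, 68.7% and 90.9% with 0. Of simulated lists, 6 of 6 shifted ones were called and 0 others. The simulated genes varied independently of each other, each with the same spread on all arrays and without slide effects. These results therefore do not cover correlated lists, dim arrays or slides.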

Results

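Gene expression was measured with 38 one-colour arrays on RNA from laser-microdissected crown roots of Nipponbare rice seedlings. Along the root, 8 stages were sampled: the root cap, the division zone, the elongation zone (from 1 to 2 mm behind the tip) and maturation zones I (2 to 3 mm), II (3 to 6 mm), III (6 to 9 mm), IV (12 to 15 mm) and V (10 to 20 mm from the root base). Across the root, 3 tissues were sampled near the tip (1 to 3 mm): an outer tissue of epidermis, exodermis and sclerenchyma, the cortex, and a stele sample that included endodermis and pericycle. The outer tissue and the stele were also sampled near the base (10 to 20 mm from it). Each group had 3 arrays except the stele near the base, which had 2, and the number of arrays limits the precision. The 75th percentile of signal ranged from 13.1 to 492 between arrays, and the outer tissue near the base was the dimmest group, with 27.4% of probes well above background against 64.0% in maturation zone I. The lowest correlation between replicates was 0.862 in the outer tissue near the base and 0.878 in the cortex, and no lower than 0.921 in every other group. Values given for a gene are log2 differences ± the standard error of the limma fit, with 3 arrays per group unless stated. Where a gene was not well above background on every array of the lower group, the value is a fold over that group's background floor, written as at least that fold. A count such as 1 of 3 gives the lower group's arrays where the gene's probe was well above background. With no count, it was on none.

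The first question was how expression changed along the root. Genes for nicotianamine, the metal chelator from which phytosiderophores are made, spanned the widest ranges of the genes named here: NAS1 (Os03g0307300, at least 17440-fold) and NAS2 (Os03g0307200, at least 15110-fold) were highest in maturation zone III and lowest in the division zone. The iron-phytosiderophore transporter YSL15 (Os02g0650300, at least 1707-fold) was highest in maturation zone I, and the xylem-loading proteins PHO1;2 (Os02g0809800, at least 449-fold) for phosphate and FRDL1 (Os03g0216700, at least 376-fold) for citrate were highest in maturation zones V and IV, all with their lowest level in the division zone. The tonoplast aquaporin TIP2;1 (Os02g0658100, at least 2757-fold, 2 of 3), the plasma membrane aquaporin PIP2;1 (Os07g0448800, 7.00) and the phosphate transporter PT8 (Os10g0444700, 5.42) peaked in the elongation zone, and the ammonium transporter AMT1;1 (Os04g0509600, at least 419-fold, 2 of 3) in maturation zone I. The sodium transporter HKT1;5 (Os01g0307500, at least 154-fold) and the potassium channel AKT1 (Os01g0648000, at least 231-fold) were highest in maturation zone V. Among genes measured in every stage, a metallothionein (Os11g0704500, 11.42) was highest in maturation zone III, an anionic peroxidase (Os04g0689000, 9.16) in the division zone, the root-specific RCc3 (Os02g0662000, 8.79) in the elongation zone, an ERF2-type transcription factor (Os09g0434500, 8.09) in maturation zone IV and a 4-coumarate-CoA ligase-like gene (Os04g0683700, 8.06) in maturation zone V. A histone H4 (Os04g0583600, 7.42) fell from its peak in the division zone to its lowest level in maturation zone V. A moderated F test called 18319 of 20399 genes (89.8%) as changing by at least 2-fold, and 5804 of them ranged over 16-fold or more.

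For 17305 of the 18319 genes called, the stage with the highest mean, which was not tested against the next highest, was well above background on every array. The division zone held 6112 of them (35.3%), maturation zone V 2586, the elongation zone 2535 and the root cap 2409, against 1778 in maturation zone III, 830 in I, 691 in IV and 364 in II. Genes of growth by division peaked in the division zone: 225 of 236 cytosolic ribosomal proteins, 39 of 45 core histones, 32 of 49 mitotic genes and 23 of 28 DNA replication genes. The elongation zone was the peak of 37 of 95 class III peroxidases, 19 of 44 lignin genes and laccases, 14 of 35 extensins and arabinogalactan proteins, 9 of 20 cellulose synthases, 7 of 14 aquaporins and 4 of 7 phosphate transporters. Starch genes peaked in the root cap (10 of 21), as did 11 of 37 expansins and 5 of 10 cytokinin genes, while metal uptake genes peaked most often in maturation zone III (8 of 22). Maturation zone V was the peak of 41 of 48 photosynthesis genes and 54 of 208 MYB, NAC and WRKY transcription factors. Other lists were spread over the stages. Auxin genes peaked most often in the elongation zone (21 of 69), heat shock proteins in the division zone (37 of 100), sugar transporters in maturation zone V (7 of 28) and ethylene genes in the elongation zone (9 of 46). The defence protein list peaked in the root cap, the division zone and maturation zone V in 21, 21 and 21 of 124 cases. Its word thionin also matched methionine genes, such as an S-adenosylmethionine synthetase (Os01g0323600), so these are not counts of defence proteins alone. The share of members that varied was 13 of 14 for nitrate and ammonium transporters, 10 of 14 for gibberellin genes, 18 of 24 for low oxygen metabolism, 6 of 7 for suberin and Casparian strip genes and 2 of 3 for diterpenoid and kaurene synthesis.

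**Figure D1:**
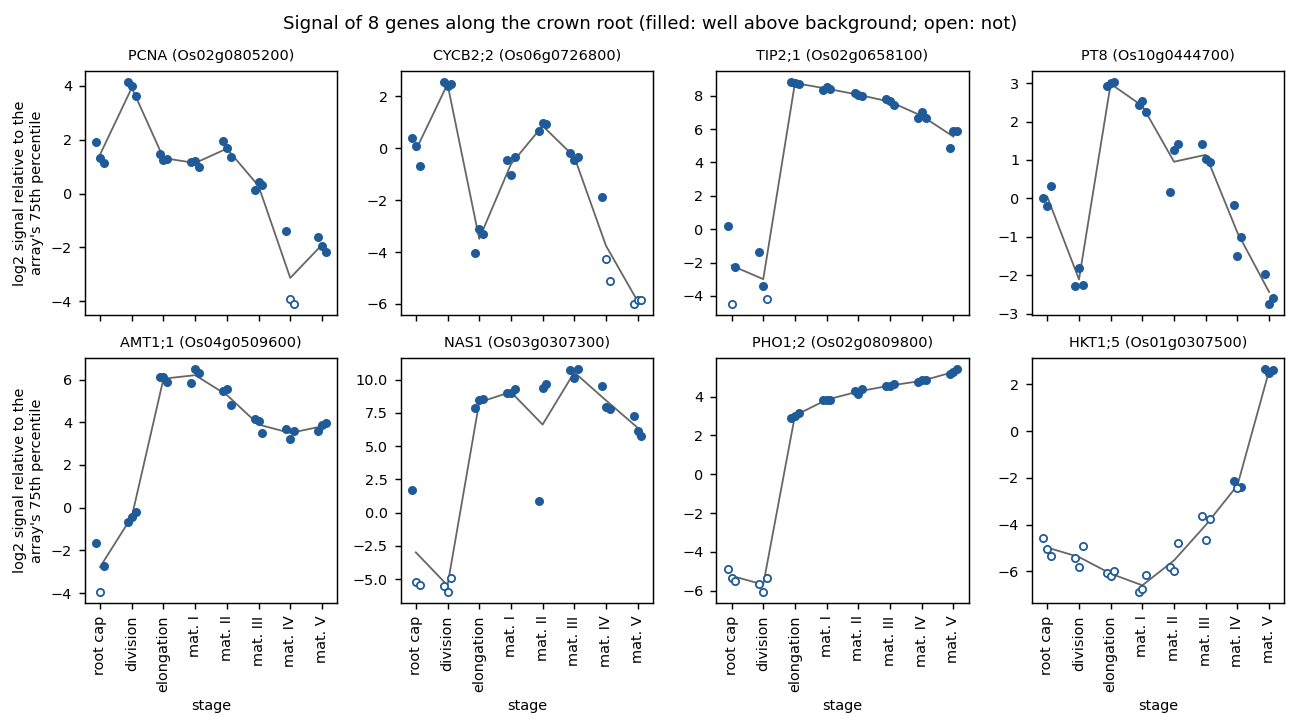
Log2 signal relative to the array's 75th percentile of 8 genes in the 8 stages, from the root cap to maturation zone V; points are single arrays (filled where well above background, open where not) and the line joins the stage means. The cell cycle genes PCNA and CYCB2;2 peaked in the division zone. NAS1 and PHO1;2 had their lowest mean there, where they were not well above background on any array.

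The division zone was compared with the root cap to find what set the meristem apart from the cap in front of it. Genes of cell proliferation were higher in the division zone: the sliding clamp PCNA (Os02g0805200, 2.48 ± 0.43), the mitotic cyclin CYCB2;2 (Os06g0726800, 2.55 ± 0.59), the mitotic kinase CDKB2;1 (Os08g0512600, 2.05 ± 0.49) and the helicase subunit MCM5 (Os02g0797400, 1.92 ± 0.55). A cyclin A2 (Os12g0502300, 2.70 ± 0.37), a histone H3 (Os11g0155900, 3.17 ± 0.59) and a histone H4 (Os07g0549900, 2.50 ± 0.23) were higher too. The ribosomal proteins L21 (Os03g0141000, 2.81 ± 0.54) and L31 (Os06g0319700, 2.56 ± 0.34) rose with them. The stele transcription factor SHR1 (Os07g0586900, at least 21.7-fold) and the aquaporin PIP2;5 (Os07g0448200, at least 19.4-fold) were not well above background in the root cap. Myo-inositol-1-phosphate synthase (Os03g0192700, 6.29 ± 0.40) and RCc3 (Os02g0662000, 5.56 ± 0.63) rose too. Lower in the division zone, and so higher in the cap, were an endochitinase (Os06g0726200, -9.56 ± 0.50), an extensin-like protein (Os05g0552600, -8.95 ± 0.72), UDP-glucose 4-epimerase (Os05g0595100, -8.69 ± 0.42) and a xyloglucan fucosyltransferase (Os04g0449200, -7.61 ± 0.91), which acts on wall polysaccharides. The root cap family genes Os01g0968300 (at least 1150-fold) and Os01g0968200 (at least 557-fold), an ACC oxidase (Os01g0580500, at least 924-fold) of ethylene synthesis, a peroxidase (Os07g0677100, at least 718-fold) and an ammonium transporter (Os01g0831900, at least 84.7-fold) fell to background. Starch genes fell too, among them an ADP-glucose pyrophosphorylase large subunit (Os05g0580000, -3.85 ± 0.78) and a granule-bound starch synthase (Os07g0412100, -3.26 ± 0.65). The transcription factors ERF3 (Os05g0361700, -5.56 ± 0.58), an EIN3-family protein (Os07g0685700, -4.64 ± 0.20) and WRKY53 (Os05g0343400, -3.99 ± 0.34) were lower as well.

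In this comparison limma called 8655 genes, 4307 higher and 4348 lower in the division zone, and the highest adjusted p among the genes named was 0.00381. Of these genes, MCM5 did not pass with slide as a block. Cytosolic ribosomal proteins had the smallest camera p of the lists: 191 of 236 rose, 0 fell and 45 did not pass (193 passed when adjusted over the list alone), with a camera adjusted p of 2.21e-27 that was 0.365 with an estimated correlation. Of 45 core histones 36 rose, and of 28 DNA replication genes 22 rose, 1 fell and 5 did not pass (23 adjusted over the list alone). Their adjusted p values of 1.79e-08 and 0.000232 became 0.217 and 0.378 with an estimated correlation. Of 21 starch genes, 2 rose, 10 fell and 9 did not pass (adjusted p 0.0168, and 0.529 with an estimated correlation). The split of calls depended on the scaling: with arrays scaled on their median, which moved the median of all genes by 0.37, 6335 genes were higher and 3529 lower, and with the percentile taken over probes well above background on all arrays (shift -0.26) 3189 and 5181. With slide as a block 7944 genes passed. Within slide 1, which held all root cap arrays and 1 of the division zone, 7884 passed, and the 10 called lists kept their sign there, while 9 of them stayed called with the block.

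In limma, 909 genes passed as higher in the root cap than in all 7 other stages. Among them, with the difference to the nearest other stage, were an extensin-like protein (Os05g0552600, 8.95), the expansin EXPA13 (Os02g0267200, at least 172.6-fold), a pollen allergen Lol pI-type protein (Os05g0246300, 8.04), the xyloglucan fucosyltransferase (Os04g0449200, 7.61), an aspartic peptidase (Os01g0936900, 7.18), cytokinin dehydrogenase 1 (Os01g0187600, 6.43) and a root cap family protein (Os04g0410400, 6.29). The root cap family genes Os01g0968300 (at least 433-fold) and Os01g0968200 (at least 209.8-fold) and the ACC oxidase (Os01g0580500, at least 348-fold) were not well above background in the nearest stage. Measured genes, well above background in the cap and 2-fold over the floor, numbered 792 of the 909. They held 8 of 37 expansins, 7 of 35 extensins and arabinogalactan proteins, 6 of 21 starch and 8 of 69 auxin genes.

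Between the division and elongation zones, where cells stop dividing and expand, the proliferation genes fell: CYCB2;2 (-5.96 ± 0.59), CDKB2;1 (-4.92 ± 0.49), PCNA (-2.61 ± 0.43) and MCM5 (-2.43 ± 0.55). So did a histone H3 (Os05g0438700, -5.64 ± 0.77), a histone H2A (Os05g0113900, -5.27 ± 0.50), a histone H4 (Os03g0119900, -5.07 ± 0.28), DNA polymerase alpha subunit B (Os12g0242900, -3.70 ± 0.57) and replication protein A1 (Os03g0214100, -3.60 ± 0.52). The ribosomal proteins L21 (Os03g0141000, -4.46 ± 0.54) and L31 (Os06g0319700, -4.30 ± 0.34) fell with them, and other decreases were those of a Bowman-Birk inhibitor (Os01g0127600, -10.05 ± 1.11) and a thionin (Os06g0514100, -9.68 ± 0.76), both defence proteins. Uptake and transport genes rose: AMT1;1 (6.46 ± 0.34) and AMT1;3 (Os02g0620600, at least 52.0-fold) for ammonium, PT8 (5.09 ± 0.41) for phosphate, HAK1 (Os04g0401700, 5.35 ± 0.62) and AKT1 (at least 28.8-fold) for potassium, NRAMP5 (Os07g0257200, at least 12.7-fold) for manganese and the silicon transporters LSI1 (Os02g0745100, at least 809-fold) and LSI2 (Os03g0107300, at least 25.4-fold). For iron there were NAS1 (at least 3654-fold), NAS2 (at least 3472-fold), YSL15 (at least 1084-fold) and IRT1 (Os03g0667500, at least 71.1-fold). The xylem-loading genes PHO1;2 (at least 94.7-fold) and FRDL1 (at least 98.9-fold) and the Casparian strip protein CASP1 (Os04g0684300, at least 222-fold) also appeared. The aquaporin PIP2;1 (4.60 ± 0.19), a tonoplast aquaporin (Os03g0146100, 6.21 ± 0.18) and a plasma membrane aquaporin (Os04g0559700, 9.48 ± 0.60) rose as cells expanded. Wall genes rose as well, with the primary wall cellulose synthase CESA3 (Os07g0424400, 4.38 ± 0.12), the secondary wall synthase CESA4 (Os01g0750300, at least 44.8-fold) and the root hair gene CSLD1 (Os10g0578200, at least 24.7-fold). The phenylpropanoid and lignin genes among the rises were the phenylalanine ammonia-lyases Os02g0626400 (5.28 ± 0.22) and Os05g0427400 (5.27 ± 0.62), a cinnamyl-alcohol dehydrogenase (Os02g0187800, 4.87 ± 0.28) and a dirigent protein (Os07g0636800, at least 224-fold). The microtubule-associated MAP65 (Os09g0450300, 7.25 ± 0.16) rose too.

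Limma called 12794 genes in this step, 5960 higher and 6834 lower in the elongation zone, with a highest adjusted p of 0.000257 among the genes named. Every one of the 229 cytosolic ribosomal proteins that passed fell, out of 236 (adjusted p 2.51e-33 by camera, 0.297 with an estimated correlation). Of 45 core histones, 1 rose and 38 fell (adjusted p 4.82e-10, 0.187 with an estimated correlation), and 25 of 28 DNA replication genes fell (25 adjusted over the list alone). Of 44 lignin genes and laccases 37 rose and 7 did not pass (adjusted p 3.40e-10, 0.160 with an estimated correlation), and of 14 aquaporins 12 rose and 1 fell (adjusted p 7.79e-06, 0.187 with an estimated correlation). Class III peroxidases divided into 66 that rose and 15 that fell of 95, and 15 of 22 metal uptake genes, 10 of 14 nitrate and ammonium transporters and 19 of 28 sugar transporters rose. Scaling on the median moved the median of all genes by -0.33, and normexp by -0.15. With slide as a block 12285 genes passed, and within slide 2, with 2 arrays of each zone, 12613. The median of the ribosomal list was -3.06 over all arrays and -2.97 with the block or within slide 2, which are the same estimate.

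From the elongation zone to maturation zone I some cell cycle genes rose again: the mitotic cyclins CYCB2;2 (2.87 ± 0.59) and CYCB2;1 (Os04g0563700, at least 6.37-fold) and the cyclins Os01g0805600 (2.95 ± 0.40) and Os05g0493500 (3.02 ± 0.57). The same held for the cell plate syntaxin KNOLLE (Os03g0736500, 2.91 ± 0.40), an HMG box protein (Os02g0258200, 3.18 ± 0.45) and a histone H2A (Os08g0427700, 1.66 ± 0.27). The silicon efflux transporter LSI2 (1.56 ± 0.34) rose as well. Expansins, which loosen walls, dropped out: EXPB5 (Os04g0552200, at least 97.6-fold), EXPA3 (Os05g0276500, at least 35.7-fold) and EXPA18 (Os03g0155900, at least 16.2-fold) were not well above background in maturation zone I. Also lower were the Casparian strip protein CASP1 (-3.35 ± 0.76), the sodium transporter HKT2;1 (Os06g0701700, -2.55 ± 0.51), cinnamate 4-hydroxylase (Os02g0467000, -2.67 ± 0.60), the peroxidases Os06g0681600 (-4.33 ± 0.54) and Os01g0263000 (-4.27 ± 0.55), a lipid transfer protein (Os12g0115500, -4.24 ± 0.53) and a SAUR auxin-responsive gene (Os08g0452500, -2.87 ± 0.40). Of 45 core histones 12 rose, 0 fell and 33 did not pass, with 20 adjusted over the list alone (camera adjusted p 1.15e-10, 0.187 with an estimated correlation). Mitotic genes rose in 15 of 49 cases (adjusted p 5.56e-05, 0.365 with an estimated correlation). Of 37 expansins 2 rose and 9 fell (adjusted p 0.000351, 0.529 with an estimated correlation), and 7 of 44 lignin genes fell.

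These adjoining zones were close, with 1157 genes called by limma, 627 higher and 530 lower, and a highest adjusted p of 0.00399 among the genes named. Of these genes, LSI2 and Os02g0467000 did not pass with quantile normalization, nor did CYCB2;2, Os08g0427700, CASP1, HKT2;1 and Os02g0467000 with slide as a block. The count rested on single arrays: it was 626 without elongation zone replicate 1 and 732 without maturation zone I replicate 3. With slide as a block 226 genes passed, and within slide 3, which held all maturation zone I arrays and 1 of the elongation zone, 1021. The core histone median was 1.03 over all arrays and 0.90 with the block or within slide 3, which are the same estimate. The split moved with the scaling: 542 higher and 735 lower on the median (shift of all genes -0.12), 340 and 500 with normexp, and 860 and 414 with the percentile over probes well above background on all arrays (shift 0.14).

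Maturation zone II was then compared with zone I. Higher in zone II were a topoisomerase I-like gene (Os05g0115100, 5.56 ± 0.48), a dormancy/auxin-associated protein (Os09g0437500, 2.04 ± 0.27), the histones H4 Os10g0539500 (1.56 ± 0.22) and Os09g0433600 (1.15 ± 0.18), a thionin (Os03g0130300, at least 15.4-fold, 1 of 3) and a zinc finger protein (Os04g0168100, at least 34.0-fold). An allergenic protein (Os07g0215500, at least 40.2-fold) and the seed storage glutelin B1 (Os02g0249900, at least 43.8-fold, 1 of 3) rose from near background. The glutelin call rested on single arrays, with an adjusted p of 0.105 without maturation zone II replicate 1 and 0.0529 without maturation zone I replicate 1. Lower were a xyloglucan fucosyltransferase (Os02g0763800, -2.32 ± 0.48) and a xyloglucan endotransglycosylase (Os02g0280300, at least 4.81-fold, 2 of 3), which act on the cell wall, a tonoplast aquaglyceroporin (Os01g0232000, at least 6.96-fold, 2 of 3), an exostosin-like protein (Os03g0144300, at least 5.51-fold, 2 of 3) and a peroxidase (Os03g0368600, -2.37 ± 0.45). Of 45 core histones 5 rose and 40 did not pass (camera adjusted p 1.53e-09, 0.187 with an estimated correlation, median 0.75). The metal uptake list shifted down with a median of -0.49 although 0 of its 22 members passed limma (adjusted p 0.000322, 0.365 with an estimated correlation), and 19 of them varied along the stages by the F test. This shift rested on zone II replicate 1, which stood apart in iron genes: NAS1 was at 0.85 there against 9.35 and 9.67 on the other zone II arrays, and YSL15, which is not on the list, at -1.01 against 6.31 and 6.20. Without that array the list median was -0.18 and its adjusted p 0.147.

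Limma called 627 genes, 415 higher and 212 lower, with a highest adjusted p of 0.0102 among the genes named. Of these genes, Os09g0433600 did not pass with normexp. The count depended strongly on single arrays: 193, 914 and 253 genes passed without maturation zone II replicate 1, 2 and 3, and 254, 210 and 326 without maturation zone I replicate 1, 2 and 3. The calls split into 450 higher and 410 lower on the median (shift of all genes -0.14), and 206 and 214 with quantile normalization, and normexp moved the median of all genes by 0.17. Each group lay on a slide of its own, so slide and stage cannot be told apart.

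The next step led from maturation zone II to III. Lower in zone III were a cellulase (Os04g0674800, -5.52 ± 0.76), actin 7 (Os12g0163700, at least 20.7-fold), the secondary wall synthases CESA7 (Os10g0467800, -2.41 ± 0.65) and CESA4 (-1.80 ± 0.48), a laccase (Os11g0708100, -2.70 ± 0.37) and a dirigent protein (Os07g0638500, at least 29.7-fold, 1 of 3). The peroxidases Os07g0676900 (-2.97 ± 0.79) and Os05g0135500 (-2.59 ± 0.51), a kinesin-like protein (Os08g0547500, -1.57 ± 0.34), the ribosomal protein L11 (Os06g0550000, -1.68 ± 0.41) and catalase A (Os02g0115700, -3.05 ± 0.60) also fell. Higher were NRAMP5 (1.64 ± 0.37), a metallothionein (Os05g0111300, 3.94 ± 0.62), a Myb-related protein (Os09g0401000, 2.51 ± 0.51), the type-A response regulators Os11g0143300 (1.62 ± 0.25) and ARR17 (Os12g0139400, 1.57 ± 0.21), which respond to cytokinin, and a CYP86A1-type hydroxylase (Os01g0854800, at least 5.86-fold). Of 236 cytosolic ribosomal proteins 4 rose, 36 fell and 196 did not pass (camera adjusted p 5.78e-26, 0.365 with an estimated correlation). Mitotic genes fell in 14 of 49 cases (adjusted p 3.01e-05, 0.365 with an estimated correlation). Class III peroxidases divided into 9 that rose and 27 that fell, with a median of -0.19 that became 0.09 with normexp.

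Limma called 2999 genes, 1862 higher and 1137 lower, of which 1826 had the higher group well above background on every array and stood 2-fold over the floor. The highest adjusted p among the genes named was 0.00778. Of these genes, CESA7, CESA4, Os07g0676900, Os05g0135500, Os06g0550000 and NRAMP5 did not pass with slide as a block. Without maturation zone II replicate 2, 1822 genes passed, and with slide as a block 1316. Slide 4 held all maturation zone II arrays and 1 of zone III. There 99.9% of the called genes kept their direction, which is no separate check, because these arrays had helped choose them. The ribosomal median was -0.68 over all arrays, -0.62 with the block and -0.62 within slide 4. The split was 1729 higher and 1666 lower on the median (shift -0.16), 1332 and 1502 with quantile normalization (shift -0.13), and 1716 and 525 with normexp (shift 0.29).

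In maturation zone IV, genes of lignified walls rose over zone III: the laccases Os03g0273200 (at least 35.9-fold), Os01g0842500 (at least 25.7-fold) and Os11g0708100 (2.09 ± 0.37), a phenylalanine ammonia-lyase (Os04g0518100, 2.35 ± 0.28), the transcription factor MYB1 (Os01g0702700, at least 18.7-fold) and a plastocyanin-like protein (Os06g0218600, 4.47 ± 0.59). Some replication and nutrient genes fell: PCNA (at least 5.23-fold, 1 of 3), CYCB2;2 (at least 3.84-fold, 1 of 3), MCM5 (at least 4.98-fold, 1 of 3) and histones H4 (Os04g0583600, -2.77 ± 0.52), H2A (Os01g0502700, -2.67 ± 0.48) and H3 (Os04g0419600, -2.72 ± 0.41). With them went nicotianamine aminotransferase (Os02g0302700, -1.31 ± 0.19) of phytosiderophore synthesis and the phosphate transporter PT8 (-2.03 ± 0.41). A small heat shock protein (Os10g0159600, at least 16.5-fold, 2 of 3) and the expansins EXPA5 (Os02g0744200, at least 7.03-fold, 1 of 3) and EXPA7 (Os03g0822000, at least 4.73-fold, 1 of 3) fell too, as did the auxin response factor 2 (Os06g0702600, -1.79 ± 0.28). Core histones fell in 18 of 45 cases and 0 rose (camera adjusted p 2.27e-08, 0.217 with an estimated correlation). Metal uptake genes fell in 5 of 22 cases (adjusted p 0.00191, 0.430 with an estimated correlation), and lignin genes and laccases rose in 8 of 44 cases (adjusted p 0.0200, 0.529 with an estimated correlation, and pointing down at 0.979 over genes above background on every array).

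Limma called 1400 genes, 549 higher and 851 lower, and 865 with the higher group well above background on every array and 2-fold over the floor. The highest adjusted p among the genes named was 0.00202. Of these genes, Os02g0302700 did not pass with normexp, nor did MCM5 with slide as a block. Without maturation zone IV replicate 3 the count was 895, and without zone III replicate 3 933. With slide as a block 613 genes passed. Within slide 5, with 2 arrays of each zone, limma called 0, against 1429 at an unadjusted p under 0.05 and 2-fold. That 100% of the called genes kept direction is again no separate check. The core histone median was -0.64 over all arrays, -0.53 with the block and -0.53 within slide 5.

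Near the root base, in maturation zone V, photosynthesis genes rose over zone IV: photosystem I subunit G (Os09g0481200, 3.66 ± 0.45), a chlorophyll a/b-binding protein (Os11g0242800, 3.50 ± 0.24), the Rubisco small subunit (Os12g0291100, at least 43.5-fold, 1 of 3), plastocyanin (Os06g0101600, at least 38.5-fold, 1 of 3) and an oxygen-evolving enhancer protein (Os01g0501800, at least 36.9-fold, 1 of 3). ACC oxidase 1 (Os02g0771600, 5.23 ± 0.40) rose, as did a cinnamoyl-CoA reductase (Os09g0419200, 3.60 ± 0.24), an MtN3-type sugar transporter (Os02g0301100, 2.88 ± 0.37), the sucrose transporter SUT1 (Os03g0170900, 1.53 ± 0.36) and the sodium transporter HKT1;5 (at least 27.4-fold, 2 of 3). Lower were RCc3 (Os02g0662000, -4.90 ± 0.63), peroxidase P7 (Os06g0547400, -4.66 ± 0.56), a chitinase (Os06g0356800, -4.58 ± 0.78), a laccase (Os01g0842500, -3.91 ± 0.63), a beta-expansin (Os02g0658800, at least 35.6-fold), the glutelins Os02g0249800 (at least 34.0-fold) and Os02g0249900 (at least 33.1-fold) and PT8 (-1.55 ± 0.41). Of 48 photosynthesis genes 36 rose, 1 fell and 11 did not pass (40 passed adjusted over the list alone), with a median of 3.21 and a camera adjusted p of 4.60e-25, which was 0.187 with an estimated correlation. Class III peroxidases divided into 3 that rose and 37 that fell (adjusted p 4.10e-07, 0.365 with an estimated correlation), and expansins into 0 and 14 (adjusted p 0.000184, 0.521 with an estimated correlation). Heat shock proteins rose in 10 of 100 cases and fell in 5 (adjusted p 0.00191, 0.187 with an estimated correlation).

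Limma called 3510 genes, 903 higher and 2607 lower, and 1954 of them with the higher group well above background on every array and 2-fold over the floor. Among the genes named, adjusted p reached at most 0.00576. Of these genes, SUT1 and PT8 did not pass with normexp. The split was 1633 higher and 2270 lower on the median (shift 0.25) and 1082 and 1442 with quantile normalization (shift 0.13). Zone V was scanned on another day and on other slides than zone IV, so stage and scan day cannot be told apart.

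**Figure D2:**
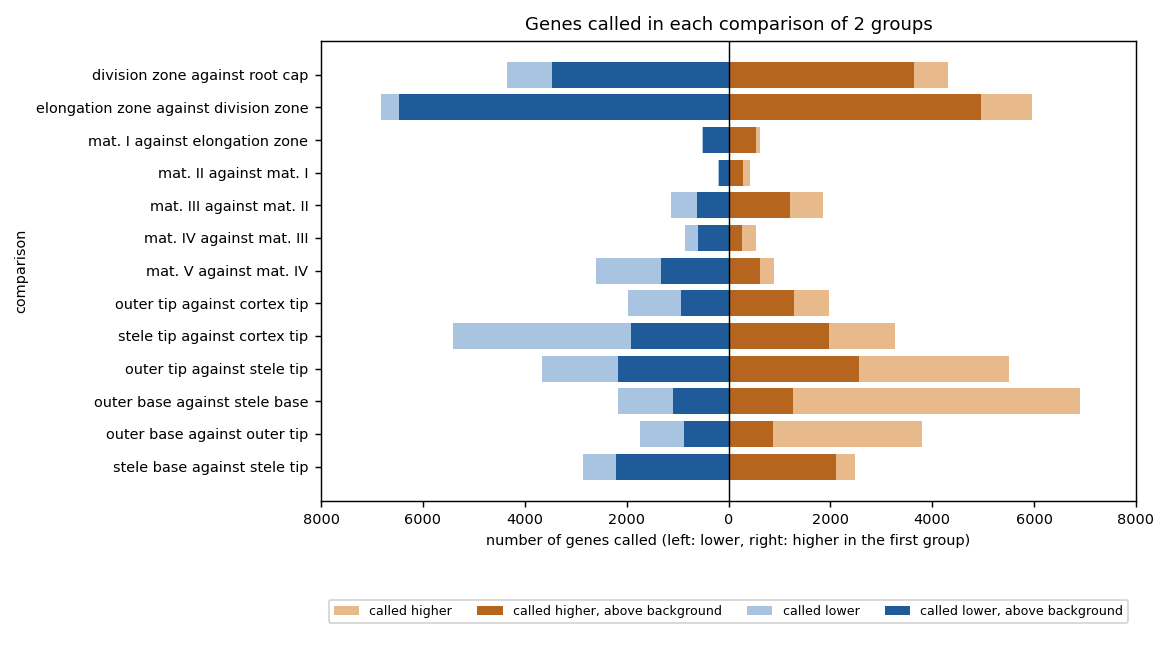
Number of genes called higher (right) and lower (left) in the first group of each of 13 comparisons, at an adjusted p under 0.05 and a change of at least 2-fold over 20399 genes tested; the darker part of each bar is the calls whose higher group was well above background on every array and 2-fold over the floor. The step from the division to the elongation zone had 12794 calls and that from maturation zone I to II 627.

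Near the tip, the outer tissue was compared with the cortex to find genes of the root surface. The secondary wall synthases CESA7 (4.95 ± 0.65) and CESA4 (at least 31.2-fold, 2 of 3) were higher in the outer tissue, which includes the sclerenchyma. So were the uptake genes HAK1 (4.76 ± 0.62), AMT1;1 (2.81 ± 0.34), AMT1;3 (at least 8.04-fold, 1 of 3), PT2 (Os03g0150800, at least 9.90-fold, 2 of 3), PT8 (1.55 ± 0.41), YSL15 (at least 34.0-fold, 2 of 3), LSI2 (at least 19.2-fold, 2 of 3) and NRAMP5 (at least 8.58-fold, 2 of 3). The outer tissue also exceeded the cortex in the lignin genes phenylalanine ammonia-lyase (Os02g0626100, 3.39 ± 0.20) and cinnamyl-alcohol dehydrogenase (Os02g0187800, 3.17 ± 0.28), another CYP86A1-type hydroxylase (Os03g0140200, 2.41 ± 0.28), peroxidase 1 (Os05g0162000, 5.36 ± 0.70), a PR-1 protein (Os10g0191300, 4.33 ± 0.62) and hemoglobin 1 (Os03g0233900, 4.75 ± 0.34). The cortex was higher in the beta-expansins Os03g0102700 (-3.24 ± 0.58) and Os10g0555600 (-2.37 ± 0.52), the aquaporins Os06g0228200 (-2.92 ± 0.54), Os02g0666200 (-2.23 ± 0.17) and PIP2;5 (-1.44 ± 0.36), a bHLH transcription factor (Os10g0544200, -3.74 ± 0.33) and a nitrate transporter (Os08g0155400, -2.09 ± 0.21). Of 44 lignin genes and laccases 17 rose and 4 fell (camera adjusted p 4.60e-05, 0.220 with an estimated correlation), and of 14 aquaporins 0 rose and 8 fell (8 passed adjusted over the list alone, adjusted p 0.000474, 0.326 with an estimated correlation). Low oxygen genes rose in 6 of 24 cases and fell in 2 (adjusted p 0.00579, 0.220 with an estimated correlation).

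Limma called 3955 genes, 1972 higher and 1983 lower in the outer tissue, and 2215 with the higher group well above background on every array and 2-fold over the floor. The highest adjusted p among the genes named was 0.00410. Of these genes, PT8 did not pass with normexp or with slide as a block. With normexp the split was 587 higher and 363 lower. With slide as a block 4235 genes passed, and within slide 8, which held all outer tissue arrays and cortex replicate 3, 1391 did. The aquaporin median was -1.25 over all arrays, -1.49 with the block and -1.49 within slide 8. Of the 7 called lists, 6 kept their sign within slide 8 and 5 stayed called with the block.

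The stele sample near the tip was higher than the cortex in the stele transcription factor SHR1 (at least 7.58-fold, 2 of 3) and the xylem-loading genes PHO1;2 (at least 19.6-fold, 2 of 3) and FRDL1 (at least 15.1-fold, 2 of 3). It was also higher in the Casparian strip protein CASP1 (at least 10.2-fold, 1 of 3), the MADS-box gene TAGL12 (Os08g0112700, at least 15.6-fold, 2 of 3) and the cytokinin response regulator ARR1 (Os01g0904700, at least 8.20-fold, 2 of 3). Ribosomal proteins such as S4 (Os02g0105900, 3.18 ± 0.21), L10a (Os02g0321900, 3.12 ± 0.24), the acidic protein P2A (Os01g0191100, 3.11 ± 0.25) and L12 (Os04g0598200, 3.05 ± 0.22) were higher. So were PCNA (1.99 ± 0.43), a histone H3 (Os04g0419600, 1.82 ± 0.41), the expansins EXPA16 (Os06g0621900, 2.66 ± 0.38) and EXPA2 (Os01g0823100, 2.46 ± 0.34), an osmotin-like protein (Os01g0839900, 4.50 ± 0.70), a peroxidase (Os04g0423800, 3.31 ± 0.47), a dirigent protein (Os07g0638500, at least 15.4-fold, 2 of 3) and CESA7 (2.07 ± 0.65). The cortex was higher in a peptidase of family M20 (Os03g0836800, -7.77 ± 0.70), peroxidase 12 (Os01g0962700, -6.51 ± 0.36), a thaumatin-like protein (Os03g0663400, -6.32 ± 0.22), a NAM/CUC2-like transcription factor (Os04g0515900, at least 247-fold, 1 of 3) and a laccase (Os05g0458300, -4.06 ± 0.26). Transport genes were higher in the cortex too: AKT1 (at least 51.5-fold, 2 of 3) and HAK1 (at least 10-fold, 2 of 3) for potassium, PT8 (at least 15.1-fold, 1 of 3), AMT1;1 (-3.20 ± 0.34), a further ammonium transporter (Os05g0468700, -2.72 ± 0.24), a nitrate transporter (Os08g0155400, -2.19 ± 0.21) and LSI1 (-2.53 ± 0.41). Among aquaporins this held for PIP2;1 (-2.33 ± 0.19), a delta-type tonoplast aquaporin (Os06g0336200, -3.14 ± 0.20) and a major intrinsic protein (Os06g0228200, -4.30 ± 0.54). The beta-expansins Os03g0102700 (-5.91 ± 0.58) and Os10g0555600 (-4.49 ± 0.52) were also cortical.

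Limma called 8691 genes, 3274 higher and 5417 lower in the stele, but only 3884 had the higher group well above background on every array and 2-fold over the floor (1970 higher and 1914 lower). Among the genes named, adjusted p reached at most 0.00767. Of 236 cytosolic ribosomal proteins 204 rose, 6 fell and 26 did not pass, with a median of 2.37 (camera adjusted p 7.75e-54, 0.187 with an estimated correlation). Of 14 nitrate and ammonium transporters 11 fell, 5 of them well above background on every cortex array, and 11 passed adjusted over the list alone (adjusted p 0.000573, 0.187 with an estimated correlation and 0.0712 with normexp). The split was 4339 higher and 3109 lower with quantile normalization (shift 0.28) and 1934 and 6843 with normexp (shift -0.38), and scaling on the median moved all genes by 0.24. With slide as a block 6671 genes passed, and within slide 9, with 2 arrays of each tissue, 6678. The ribosomal median was 2.19 with the block and 2.19 within slide 9.

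**Figure D3:**
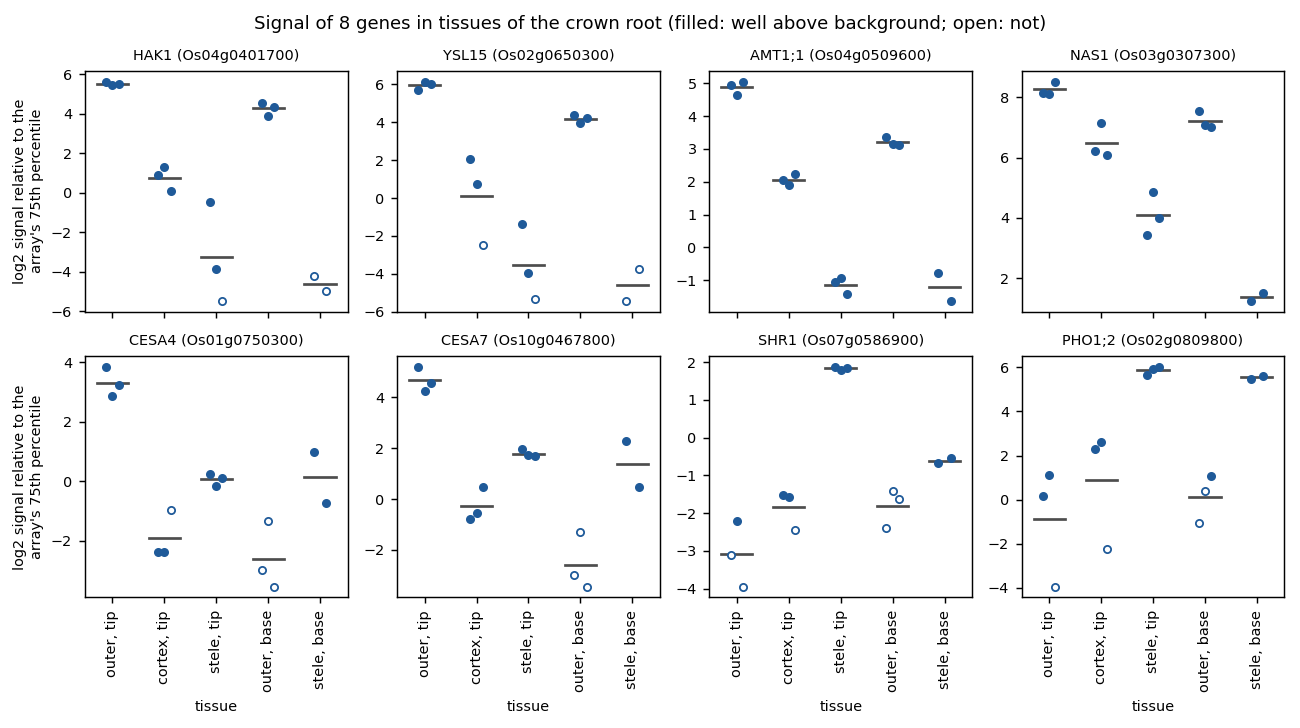
Log2 signal relative to the array's 75th percentile of 8 genes in the 3 tissues near the tip and the 2 tissues near the base; points are single arrays (filled where well above background, open where not) and short lines are group means. HAK1 and YSL15 were higher in the outer tissue than in the stele at both positions, and SHR1 and PHO1;2 were higher in the stele near the tip.

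Set against the stele directly, the outer tissue near the tip was higher in YSL15 (at least 459-fold, 2 of 3), HAK1 (at least 271-fold, 2 of 3), PT2 (at least 41.9-fold, 1 of 3), PT8 (at least 44.1-fold, 1 of 3), AKT1 (at least 39.5-fold, 2 of 3), AMT1;3 (at least 29.4-fold, 1 of 3) and AMT1;1 (6.00 ± 0.34). Outside transport it was higher in the metallothionein MT-1 (Os03g0288000, 7.62 ± 0.66), the thaumatin-like protein (Os03g0663400, 6.71 ± 0.22), a 4-coumarate-CoA ligase (Os08g0245200, 4.09 ± 0.18) and the secondary wall synthases CESA4 (3.25 ± 0.48) and CESA7 (2.87 ± 0.65). The stele was higher in SHR1 (at least 10.9-fold, 1 of 3), PHO1;2 (at least 65.0-fold, 2 of 3), FRDL1 (at least 58.2-fold, 2 of 3), CASP1 (at least 15.1-fold), TAGL12 (Os08g0112700, -5.89 ± 0.51), a peroxidase (Os04g0423800, -5.69 ± 0.47), ARR1 (Os01g0904700, at least 11.2-fold) and PIP2;5 (-2.00 ± 0.36). Higher there too were the ribosomal protein SA (Os07g0616600, -3.73 ± 0.34), P2A (Os01g0191100, -3.63 ± 0.25), a histone H3 (Os06g0160100, -2.80 ± 0.73) and a histone H4 (Os03g0119900, -2.14 ± 0.28). Of 236 cytosolic ribosomal proteins 3 rose and 209 fell (camera adjusted p 2.71e-49, 0.187 with an estimated correlation). All 7 phosphate transporters on the list rose, 4 of them well above background on every outer array (adjusted p 0.000517, 0.160 with an estimated correlation). Limma called 9190 genes, 5518 higher and 3672 lower, and 4734 with the higher group well above background on every array and 2-fold over the floor (2567 higher and 2167 lower). The highest adjusted p among the genes named was 0.00164. Of these genes, CESA4, CESA7, PHO1;2, FRDL1 and Os06g0160100 did not pass with slide as a block. The split was 3708 higher and 4783 lower with quantile normalization (shift -0.26) and 6804 and 1897 with normexp (shift 0.41), and the median scaling moved all genes by -0.14. The tissues shared no slide, and with slide as a block, which links them through the cortex arrays, 6055 genes passed, 2421 higher and 3634 lower.

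Each tissue near the tip had a set of genes higher than in both others. For the outer tissue it included, with the difference to the nearest tissue, peroxidase 1 (Os05g0162000, 5.36), HAK1 (4.76), the PR-1 protein (Os10g0191300, 4.33), MT-1 (Os03g0288000, 4.29) and BRITTLE CULM1, a protein of secondary wall cellulose (Os03g0416200, at least 32.9-fold). Its 1025 measured genes (of 1495) held 10 of 35 extensins and arabinogalactan proteins and 3 of 7 phosphate transporters.
For the cortex, over the outer tissue, it included a GRAS factor (Os05g0500600, at least 10.3-fold), the bHLH factor (Os10g0544200, 3.74) and RCc2 (Os10g0551800, at least 5.755-fold). Its 877 genes included 5 of 14 aquaporins. RCc2 did not pass with normexp.
For the stele it included the osmotin-like protein (Os01g0839900, 4.50), the ribosomal protein SA (Os07g0616600, 3.73, and 10.99-fold over floors), TAGL12 (Os08g0112700, at least 15.6-fold, 2 of 3), PHO1;2 (at least 19.6-fold, 2 of 3) and FRDL1 (at least 15.1-fold, 2 of 3). Its 1534 measured genes (of 2459) held 189 of 236 cytosolic ribosomal proteins. With slide as a block PHO1;2 and FRDL1 did not pass, and the sets held 1081 (outer), 904 (cortex) and 2379 (stele) genes.

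Near the base, with 3 outer and 2 stele arrays, the outer tissue again held the uptake genes: HAK1 (at least 155-fold), YSL15 (at least 147-fold), AMT1;3 (at least 31.1-fold), NAR2.1 (Os02g0595900, at least 27.5-fold) of nitrate uptake, NAS1 (5.83 ± 1.65), NAS2 (6.51 ± 1.65), AKT1 (6.49 ± 0.51), AMT1;1 (4.41 ± 0.38) and NRAMP5 (2.63 ± 0.42). It was also higher in a GDSL lipase (Os01g0216000, 8.82 ± 0.89), a metallothionein (Os12g0568500, 8.43 ± 1.06), the PR-1 protein (Os10g0191300, 6.55 ± 0.69), allene oxide synthase (Os02g0218800, at least 219.5-fold) of jasmonate synthesis, asparagine synthetase (Os03g0291500, at least 286-fold, 1 of 2), the monosaccharide transporter MST3 (Os07g0106200, 5.47 ± 0.45) and the CYP86A1-type hydroxylase Os03g0140200 (2.76 ± 0.32). The stele was higher in PHO1;2 (at least 35.6-fold, 1 of 3), HKT1;5 (at least 9.36-fold), CESA7 (at least 3.47-fold) and CESA3 (-1.72 ± 0.13). It also exceeded the outer tissue in the metallothionein RicMT (Os01g0974200, -6.77 ± 0.62), metallothionein 2 (Os01g0149800, -5.33 ± 0.38), the cytokinin response regulator ARR17 (Os12g0139400, -3.63 ± 0.24), alcohol dehydrogenase 1 (Os11g0210300, at least 10.8-fold) and hemoglobin 1 (Os03g0233900, -2.37 ± 0.38). Of 14 nitrate and ammonium transporters 11 rose and 1 fell, 5 of the rises with the outer arrays well above background (camera adjusted p 0.00552, 0.217 with an estimated correlation and 0.0991 with normexp). Photosynthesis genes rose in 7 and fell in 21 of 48 cases (adjusted p 0.00116, 0.633 with an estimated correlation).

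Limma called 9055 genes, 6894 higher and 2161 lower (76.1% higher), but 3912 of them were on no array of either group well above background, and 2359 had the higher group well above background on every array and 2-fold over the floor (1273 higher and 1086 lower). Among the genes named, adjusted p reached at most 0.00382. The excess of higher calls reversed on the median (4652 higher and 6585 lower, shift of all genes -0.86) and with quantile normalization (3200 and 4667, shift -0.56). It was smaller with normexp (3770 and 2078) and stayed with the percentile over probes well above background on all arrays (6509 and 2426). The 2 groups lay on slides of their own, so slide and tissue cannot be told apart.

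Whether the difference between the outer tissue and the stele changed from tip to base was tested as an interaction, given as the base minus the tip difference. Ribosomal proteins had a weaker stele bias at the base than at the tip. How much was left there depended on the scaling: the median moved all base differences by -0.86. P2A (Os01g0191100, 3.04 ± 0.38) differed by -0.60 at the base and -3.63 at the tip, and S28 (Os03g0167100, 3.12 ± 0.57) and L14 (Os04g0515300, 2.86 ± 0.22) moved the same way. An HSP70 (Os11g0703900, 2.74 ± 0.22) also shifted toward the outer tissue. The metallothionein MT-1 (Os03g0288000, -8.46 ± 1.00), hemoglobin 1 (Os03g0233900, -4.20 ± 0.51), ARR17 (Os12g0139400, -3.82 ± 0.32), the oxygen-evolving protein OEE3-2 (Os07g0544800, -4.24 ± 0.53), the chlorophyll a/b-binding protein (Os11g0242800, -2.12 ± 0.36) and CESA3 (-2.05 ± 0.18) shifted toward the stele. Of 236 cytosolic ribosomal proteins 197 rose and 0 fell (camera adjusted p 7.12e-40, 0.220 with an estimated correlation). Of 48 photosynthesis genes 25 fell (adjusted p 1.79e-08, 0.365 with an estimated correlation). Of 28 DNA replication genes 14 rose (adjusted p 0.000426, 0.418 with an estimated correlation). Their base medians were dim (outer -2.19, stele -4.16), so the rise may be background. Limma called 5469 genes, 3583 higher and 1886 lower, and 837 among the 3561 genes well above background on every array of all 4 groups (456 higher and 381 lower). Named genes had adjusted p up to 0.000106. The split was 1995 higher and 4483 lower on the median (shift -0.72), 2312 and 2464 with quantile normalization (shift -0.31) and 1052 and 1526 with normexp (shift -0.42). Each base group lay on a slide of its own.

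Within the outer tissue, the base was lower than the tip in wall and water genes: CESA7 (at least 33.6-fold), CESA4 (at least 13.2-fold), CESA3 (-2.09 ± 0.12) and CESA1 (Os05g0176100, -1.55 ± 0.17), and the aquaporins TIP2;1 (-4.10 ± 0.67) and PIP2;1 (-2.76 ± 0.19). Lower at the base as well were RCc3 (Os02g0662000, at least 117-fold), a histone H4 (Os04g0583600, at least 12.1-fold), hemoglobin 1 (Os03g0233900, -3.42 ± 0.34) and the sucrose synthase SUS2 (Os03g0401300, -2.27 ± 0.24). It was higher in the HSP70 (Os11g0703900, 4.13 ± 0.15), a cationic peroxidase (Os07g0677600, at least 99.2-fold), a dormancy/auxin-associated protein (Os09g0437500, 3.77 ± 0.27), the CYP86A1-type hydroxylase Os01g0854800 (at least 7.13-fold), AKT1 (2.21 ± 0.46), NRAMP5 (1.86 ± 0.37) and the ribosomal proteins L10a-3 (Os08g0558000, 2.90 ± 0.19) and L17-1 (Os09g0258600, 2.88 ± 0.18). Of 236 cytosolic ribosomal proteins 162 rose, 0 fell and 113 of the rises had the base arrays well above background (camera adjusted p 3.09e-27, 0.365 with an estimated correlation). Low oxygen genes fell in 10 of 24 cases and rose in 2 (adjusted p 2.50e-05, 0.160 with an estimated correlation). Aquaporins fell in 8 of 14 cases and rose in 1 (adjusted p 0.000213, 0.274 with an estimated correlation). Limma called 5535 genes, 3803 higher and 1732 lower, and 1747 with the higher group well above background on every array and 2-fold over the floor (879 higher and 868 lower). Among the genes named, adjusted p reached at most 0.000313. Of these genes, NRAMP5 did not pass with normexp. The excess of higher calls reversed on the median (1200 higher and 3805 lower, shift -0.59), with quantile normalization (2499 and 3453, shift -0.44) and with normexp (118 and 856), and was smaller with the percentile over probes well above background on all arrays (2743 and 2033, shift -0.13). The 2 groups shared no slide, so slide and position cannot be told apart.

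In the stele, the base was higher than the tip in the sodium transporter HKT1;5 (at least 120.1-fold), the sucrose transporter SUT1 (2.47 ± 0.40), the cytokinin response regulators ARR17 (Os12g0139400, 3.62 ± 0.24) and Os11g0143300 (3.25 ± 0.28), an ERF transcription factor (Os05g0316800, 4.09 ± 0.33) and the CYP86A1-type hydroxylase Os01g0854800 (at least 22.3-fold). Photosynthesis genes rose too, such as CAB2 (Os01g0600900, at least 300-fold), CAB1 (Os09g0346500, at least 193-fold), Lhca4 (Os08g0435900, 5.07 ± 0.86) and a chlorophyll a/b-binding protein (Os11g0242800, 3.45 ± 0.27). It was lower in the cell cycle genes CDKB2;1 (at least 17.9-fold), CYCB2;2 (at least 10.7-fold) and PCNA (-3.50 ± 0.48), a histone H2A (Os03g0279200, -5.67 ± 0.59) and a histone H3 (Os01g0866200, -5.00 ± 0.45), in CASP1 (at least 38.9-fold), TIP2;1 (-6.40 ± 0.75), EXPA2 (Os01g0823100, -5.64 ± 0.38) and the dirigent protein (Os07g0638500, at least 106-fold). Of 48 photosynthesis genes 37 rose and 1 fell, with a median of 4.23 (38 passed adjusted over the list alone, camera adjusted p 8.41e-15, 0.213 with an estimated correlation). Core histones fell in 30 of 45 cases (adjusted p 2.22e-11, 0.187 with an estimated correlation). Mitotic genes rose in 2 and fell in 30 of 49 cases (adjusted p 2.59e-09, 0.187 with an estimated correlation). Cytokinin genes rose in 5 and fell in 1 of 10 cases (adjusted p 0.0137, 0.223 with an estimated correlation). Limma called 5346 genes from 2 base and 3 tip arrays, 2484 higher and 2862 lower, with a highest adjusted p of 2.74e-05 among the genes named. The base arrays had a slide to themselves, so slide and position cannot be told apart.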

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

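The tests of RNA from seed tissue, of the slide that held maturation zone II, of scan day, of dim arrays near the base and of the scaling were chosen only after the result was seen.

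The difference between the outer tissue and the stele was itself different near the base and near the tip for 5469 genes by limma's test of the interaction, and that difference between positions singled out this count and the genes that follow. As log2 base difference minus tip difference, the ribosomal protein P2A (Os01g0191100) had 3.04, S28 (Os03g0167100) 3.12, L14 (Os04g0515300) 2.86 and the HSP70 (Os11g0703900) 2.74. Negative values were found for the metallothionein MT-1 (Os03g0288000, -8.46), hemoglobin 1 (Os03g0233900, -4.20), ARR17 (Os12g0139400, -3.82), OEE3-2 (Os07g0544800, -4.24), a chlorophyll a/b-binding protein (Os11g0242800, -2.12) and CESA3 (-2.05). Both groups near the base lay on slides of their own, so position and slide cannot be told apart here. Apart from the genes, 9 probes for which the files name no gene locus were well above background on every one of the 38 arrays, a signal in data that no comparison used.

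Transcripts of the seed storage glutelins were higher in maturation zone II than in zone I. The tables argue against the slide that held zone II as the source, because zone IV, on other slides, was above zone I by a median of 6.26 over 7 glutelins (4.63 to 6.94). RNA from seed tissue remains a candidate source: 11 other genes of seed storage and endosperm rose by a median of 2.72 (-0.02 to 7.52), although laser microdissection was meant to leave other tissue out and 7 of them were well above background on every zone I array. The glutelins were dim again in zone V, and expression of these genes by the root itself was not tested.

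Photosynthesis genes were higher in maturation zone V than in zone IV. Scan day as the only source is argued against, because zone V also exceeded the 9 tip tissue arrays of its own scan day by a median of 3.23 over 48 genes (quartiles 1.90 and 4.93). A share from scan day stays open. The list median was -3.32, -2.70 and -4.80 in the outer tissue, cortex and stele near the tip. It was -5.38 in the elongation zone and -5.18 in maturation zone I, both of the other scan day. RNA from shoot tissue stays open: 12 leaf genes off the list had a median of 0.69 but ranged from -0.34 to 5.05, and the members went both ways. Expression by the root near its base stays open too and was not tested.

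Near the base more genes were called higher than lower in the outer tissue against the stele. The tables argue against neither technical explanation tested. The dim arrays of the outer tissue are a candidate cause: among 1345 calls for genes well above background on every array outside these groups, 55.3% were higher, against 76.1% of all calls. A first test, replaced after its result was seen, had argued against this: among calls well above background on every array of both groups 83.9% were higher, but that choice of genes favours those bright in the dim group. Scaling on the 75th percentile of all probes was not settled: 72.8% of calls were higher with the percentile over probes well above background on all arrays, 41.4% on the median and 40.7% with quantile normalization. The median alone was the first test here and was replaced after its result was seen, because it moves all genes alike and does not show which scaling is right. A true difference between the tissues stays open and untested.

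Counts were also compared with those of other splits of the same arrays. Groups of 3 against 3 make 10 splits, too few for a share under 0.05, and in each such comparison 1 split, the real one, gave as many genes. The real count and the highest other were 8655 against 83 for the division zone against the root cap, 12794 against 0 for the elongation against the division zone, 1157 against 0 for maturation zone I against the elongation zone, 627 against 0 for maturation zone II against I, 2999 against 1 for III against II, 1400 against 38 for IV against III, 3510 against 8 for V against IV, 8691 against 46 for the stele against the cortex, 9190 against 2 for the outer tissue against the stele near the tip and 5535 against 457 for the base against the tip in the outer tissue. For the outer tissue against the cortex they were 3955 and 1556, the latter from a split that put 3 arrays of slide 8 together, and 4235 genes passed with slide as a block. Out of 100 splits, only the real one reached the F test count (18319 against 10509) and the root cap count (909 against 0). For the outer tissue set (1495 against 1720), the cortex set (877 against 2663) and the stele set (2459 against 2688) other splits gave more genes. Each had 3 splits as large, the real one included. No split count here tells the real grouping from slide, since arrays of a slide were not interchangeable. Those of the tissue sets do not tell it from other groupings. The splits with the highest counts kept the 3 outer tissue or the 3 stele arrays together under another name, which points to the structure of the tissues. For the outer tissue and cortex sets a split that put arrays of slide 8 together was also as large (1534 and 2393 genes), and with slide as a block the sets held 1081 and 904 genes.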

How the results depend on the processing

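Chosen only after the data were seen were the percentile over probes well above background on all arrays, the counts with the higher group above background, the fits without the 2 dimmest arrays, without maturation zone V or within 1 slide, slide as a block for gene lists, the list tests on genes above background in a compared group and the list tests with each array left out.

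Of the 20 counts, all stayed within 1.5 times the reported value on the median and with the replicate number as a block, and so did all those computed on the deposited series table (19), on the percentile over probes well above background (19), with slide as a random block (8), without the 2 dimmest arrays (8), without maturation zone V (2) and within slides 1, 2, 3 and 9.

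Quantile normalization gave 695 for maturation I against elongation zone. With normexp the counts were 4906 for division zone against root cap, 1017 for II against I, 377 for IV against III, 961 for V against IV, 950 for outer tissue against cortex, 5848 for outer tissue against stele at the base, 2578 for the interaction, 974 for outer base against tip, 2858 for stele base against tip, 546 for the root cap set, 416 for the outer set, 210 for the cortex set and 1553 for the stele set. Without a filter they were 7021 for III against II, 16906 for stele against cortex, 17508 for outer tissue against stele at the tip and 17704 for outer tissue against stele at the base. Restricted to genes well above background on every array of the fit, which tests fewer genes, they were 2573 for the F test, 1135 for division zone against root cap, 1657 for elongation against division zone, 72 for maturation I against elongation zone, 116 for II against I, 305 for III against II, 150 for IV against III, 281 for V against IV, 335 for outer tissue against cortex, 1047 for stele against cortex, 997 for outer tissue against stele at the tip, 761 for outer tissue against stele at the base, 651 for the interaction, 715 for outer base against tip, 616 for stele base against tip, 62 for the root cap set, 129 for the outer set, 85 for the cortex set, 250 for the stele set and 30 for lists. Counting every probe gave 1384 for the cortex set. Slide as a block gave 226 for maturation I against elongation zone, 1316 for III against II, 613 for IV against III and 6055 for outer tissue against stele at the tip. A variance trend with robust fitting and array weights gave 2168 for maturation I against elongation zone and 1855 for II against I, and only the compared arrays 2033 for maturation I against elongation zone, 1017 for II against I, 382 for IV against III, 2467 for outer tissue against cortex, 5992 for outer tissue against stele at the base and 2662 for outer base against tip. Calls with the higher group above background and 2-fold over the floor, fewer by construction, numbered 1826 for III against II, 865 for IV against III, 1954 for V against IV, 2215 for outer tissue against cortex, 3884 for stele against cortex, 4734 for outer tissue against stele at the tip, 2359 for outer tissue against stele at the base, 1747 for outer base against tip, 576 for the cortex set and 1534 for the stele set, and 837 for the interaction when measured on every array of its 4 groups. On slide 4 limma called 0 for III against II (3811 at an unadjusted p under 0.05 and 2-fold) and on slide 5 0 for IV against III (1429), and on slide 8 it called 1391 for outer tissue against cortex, each on 4 arrays. Except where fewer genes are named or a count is fewer by construction, the cause was not tested.

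Leaving out each array in turn gave 18095 to 18350 for the F test, 7923 to 8691 for division zone against root cap, 12443 to 12665 for elongation against division zone, 626 to 1052 for maturation I against elongation zone, 193 to 914 for II against I, 1822 to 3247 for III against II, 895 to 1593 for IV against III, 2625 to 3279 for V against IV, 3569 to 4425 for outer tissue against cortex, 7800 to 8878 for stele against cortex, 8593 to 9102 for outer tissue against stele at the tip, 7641 to 9588 for outer tissue against stele at the base, 4380 to 6120 for the interaction, 4273 to 7241 for outer base against tip, 4276 to 5257 for stele base against tip, 833 to 912 for the root cap set, 1189 to 1940 for the outer set, 750 to 991 for the cortex set and 2280 to 2539 for the stele set. Where 1 of the 2 stele arrays near the base was left out, the lone array was assumed to vary like the other groups.

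Of 350 list tests, 126 passed with camera. With an estimated correlation 0 passed in limma's camera, against 45 at an unadjusted p under 0.05, on genes above background on every array 30 (fewer genes) and with fry 200. With arrays left out the number was 118 to 130. Among the lists named, camera turned round lignin genes and laccases in IV against III, on genes above background on every array (adjusted p 0.979, range over its alternatives 0.000375 to 0.979). The median of class III peroxidases in III against II changed sign with normexp (0.09), although camera kept that list down. Among the named genes 5205 of 5237 values under another setting kept their direction and call, and 32 lost the call. That share is flattered, since genes whose call ended when 1 array was left out were mostly not named. Of 730 values of named lists 675 kept both and 54 lost the call. Signal over background limited what was measured: in the outer tissue near the base 27.4% of probes were well above background, the lowest share of the 13 groups.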

Other observations

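Several genes of the fixed lists, not described with the comparisons, spanned wide ranges along the root, given here between the stages of highest and lowest mean. In lignin synthesis, a caffeic acid O-methyltransferase (Os08g0157500, at least 2915-fold, 1 of 3) peaked in the elongation zone and a cinnamoyl-CoA reductase (Os08g0441500, at least 569-fold, 2 of 3) in maturation zone IV, both lowest in the division zone. A GH3 auxin-responsive gene (Os01g0785400, at least 383-fold) was highest in the root cap and lowest in maturation zone I. Hemoglobin 4 (Os03g0234100, at least 326-fold) peaked in the elongation zone and an Hsp20 protein (Os10g0159700, at least 103-fold) in maturation zone III, both lowest in zone V. The isoamylase-type ISO2 (Os05g0393700, at least 38.9-fold) of starch debranching was highest in maturation zone III and lowest in the elongation zone. In kaurene metabolism, an ent-kaurene oxidase (Os06g0570100, at least 8.90-fold, 1 of 3) peaked in the elongation zone and was lowest in the root cap, whereas an ent-kaurenoic acid oxidase (Os06g0110000, at least 32.0-fold) peaked in zone V and was lowest in the elongation zone.

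The median log2 signal of the 48 photosynthesis genes, relative to the array's 75th percentile, was 1.12 in maturation zone V, 0.09 in the stele and -1.54 in the outer tissue near the base, -3.08 in maturation zone IV and -5.38 in the elongation zone. Of these genes, 46 were well above background on every array in maturation zone V, 39 in the stele near the base and 8 in the outer tissue there.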
